A study of Mus musculus with 4 samples.

How the data were processed

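RNA was sequenced from dissected cerebral cortex of C57BL/6 mouse embryos at embryonic day 16 (E16), from WT animals and animals with a Cd93 knockout (KO). Total RNA went into an Illumina TruSeq RNA kit and the libraries were read on a HiSeq instrument, per the labels. The labels give 4 libraries, WT 1, WT 4, KO 5 and KO 6, although the design text speaks of triplicates. They do not say that each library came from its own animal, so a p for a single gene in the fits made here measures the spread between these libraries. Most tests of lists and terms use genes as units instead. The authors' p-values compare 1 library with 1 library. The numbers do not pair the genotypes. The authors' 2 deposited tables each hold 1 KO and 1 WT library, KO 6 with WT 1 (table A) and KO 5 with WT 4 (table B).

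Each table holds whole counts per Ensembl gene, per the file headers, and the counts were made by the authors. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the build mm9, without the role of each tool and without the strand setting of the counting. The gene positions in the deposited tables are those of GRCm38, not mm9. Of the 23328 genes, 23279 are in GENCODE mouse release 21, which is on GRCm38, and 92.2% of those have its start and end. Positions are printed as deposited, counted from 1. The authors' deposited normalized values are CPM, each count scaled to its library's total, with a count of 0 written as 0.5 read. The deposited fold change is the ratio of KO to WT CPM in a table, in all of its genes, and the deposited log2 fold change is its logarithm. The deposited p-value and adjusted p-value compare 1 library with 1 library, by a tool the headers do not name. The authors marked a gene as significant exactly where the deposited adjusted p-value was under 0.05 and the change at least 2-fold.

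The listed counts made up 99.98% of the total behind the authors' CPM in each library. They summed to 17586157 in WT 1, 17158867 in WT 4, 17555476 in KO 5 and 16318317 in KO 6. A single count was 0.0569 to 0.0613 CPM, and 3 counts, the floor used for a gene without counts, were 0.171 to 0.184 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. A table lists a gene only with at least 2 counts over its 2 libraries. Table A lists 22025 genes and table B lists 21688, of which 20385 are in both and were analysed. The other 2943 are in 1 table only and enter only the closing section and an alternative. The genes of the mitochondrial genome took 3.02% to 4.16% of the counts, and the 10 most abundant genes 5.81% to 6.34%. The libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 17.6 for WT and 19.4 for KO.

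Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. After filterByExpr of edgeR, 16371 genes were tested. TMM factors were 0.994 to 1.012, and CPM values in the text are scaled by them. KO was compared with WT by edgeR's quasi-likelihood test with 2 libraries per genotype and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Log2 fold changes are KO over WT, and ± gives the SD over the 2 libraries of a genotype unless an SE is named. Ratios within a table use log2 CPM with a prior count of 2. A deposited table can stand for a shared run or day, so values within each table, and values with the table as a block in the model, stand beside the pooled ones. The tables' log2 ratios were set against each other across genes, which are not independent replicates, so no p is given for that.

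Before the data were examined, 41 gene lists, the comparisons, the tests and most alternatives were fixed. The lists were 1 of genes the study names, 20 of cell types and regions, 14 of pathways, 1 of the genes around Cd93 and 5 of technical signals. Each list was tested with camera of limma at a preset correlation of 0.01 and at an estimated correlation, and with fry, with adjustment over the lists. Ranges of a list's adjusted p leave out fry's mixed test, which has no direction. Gene ontology terms carried by the tables, with 10 to 500 tested genes, were tested for enrichment of called genes. The genes named are Cd93, Mmrn2 and Zfp503 from the study title and Itgb1, then up to 12 genes per direction with the largest change among those that passed. Where fewer than 6 passed in a direction, the genes of smallest p filled it to 6, and each list contributes up to 4 members of smallest p. Genes outside that rule are said to have been chosen after their values were seen.

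The scripts were tested on simulated counts of this comparison, in 3 simulations over 16128 genes with 200 genes changed in each. The changed genes were drawn from those with an average log2 CPM of at least 1, so recovery of genes with lower counts was not simulated. The edgeR test without a block recovered 37.0% of the genes changed 2-fold and 85.0% of those changed 4-fold, and 0.5% of its calls were false. With the table as a block it recovered 78.3% and 99.3%, and 10.4% of its calls were false. In simulations without a change the test without a block made 0 calls and the test with a block 12. For a list moved as a whole, camera at the preset correlation called it in 3 of 3 simulations and at the estimated correlation in 0 of 3. Of 300 lists that were not moved, the preset correlation called 0 without a block and 1 with it. Each gene was simulated on its own, and these lists were drawn at random. The rates therefore do not hold for lists whose genes vary together. The estimated correlation was 0.57 for the ganglionic eminence list and 0.848 for the meninges list. The simulated means followed the deposited tables, and the dispersions came from the fit with the table as a block.

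The alternatives were other normalizations (DESeq2's size factors and upper quartile), DESeq2, limma-voom, no filter, a mean count of 10, both ways of blocking libraries in pairs, leaving out each library, a 2-fold minimum, and leaving out hemoglobin, mitochondrial and sex-linked genes. After the data were seen, these were added: genes of either table, protein-coding genes only, blocked limma-voom and blocked DESeq2, DESeq2 and limma-voom for Cd93, the estimated correlation with a block, and camera over the terms. The closing section also used overlaps of 25-base words between retrocopies and their parent genes in GENCODE transcripts. Groups of 2 libraries are too small for a test of single libraries far from the rest or for other splits of the samples.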

Results

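The study's title places CD93, a transmembrane C-type lectin receptor known mainly from endothelial cells, upstream of astrogenesis, together with its ligand MMRN2 and the transcriptional repressor ZFP503. Transcriptomes of the E16 cerebral cortex, a stage at which neurogenesis gives way to the first gliogenesis, were compared between 2 WT libraries (WT 1, WT 4) and 2 Cd93 KO libraries (KO 5, KO 6). Their depths were alike, from 16318317 counts in KO 6 to 17586157 in WT 1.

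Cd93 was lower in both KO libraries than in both WT libraries. The gene (ENSMUSG00000027435, chromosome 2, 148436640 to 148443563, minus strand) had 680 counts in WT 1, 409 in WT 4, 111 in KO 5 and 99 in KO 6. Its level was 31.1 ± 10.1 CPM in WT and 6.22 ± 0.166 CPM in KO (SD, n = 2 each), 5.01-fold lower. The order of the 4 libraries follows their genotype labels. Which part of the gene was deleted is not given, so the remaining counts cannot be placed in it. Other endothelial genes did not share this drop in both tables: of 27, 1 was as low in KO 6 against WT 1, 0 in KO 5 against WT 4 and 0 in both. The log2 fold change was -2.32 (SE 0.25), with an adjusted p of 0.211 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the fourth smallest p of 16371. It was -2.63 and -1.90 within tables A and B. With the table as a block edgeR gave -2.29 and an adjusted p of 0.000971, without WT 1 it gave -1.95 and 1.63e-05, and without WT 4 -2.61 and 4.13e-09, while the adjusted p over all alternatives ran up to 0.9998 with limma-voom.

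Zfp503, which encodes a zinc-finger repressor expressed in the developing striatum, had lower counts in both KO libraries, and its WT libraries lay far apart. The gene (ENSMUSG00000039081, chromosome 14, 21983959 to 21989601) had 517 counts in WT 1 and 122 in WT 4, against 43 in KO 5 and 77 in KO 6. The level was 18.1 ± 15.5 CPM in WT and 3.60 ± 1.62 CPM in KO (SD, n = 2 each), a log2 fold change of -2.34 (SE 0.66) that did not pass, with an edgeR adjusted p of 0.9999. Within tables A and B the log2 ratio was -2.59 and -1.502. The edgeR fit with the table as a block called it, at -2.14 with an adjusted p of 0.0106, as did the fit without WT 4, at -3.01 with 1.74e-08. Without WT 1 the log2 fold change was -0.996, and the adjusted p over the alternatives ran from 1.74e-08 to 1. WT 1 also carried the highest levels of ganglionic eminence and meningeal genes, given further on.

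Mmrn2, the gene of the extracellular matrix ligand multimerin-2, and Itgb1, the gene of the integrin beta-1 subunit, did not pass the test. Mmrn2 (ENSMUSG00000041445, chromosome 14, 34375504 to 34404287) was at 5.59 ± 1.01 CPM in WT and 5.64 ± 0.138 CPM in KO, a log2 fold change of 0.01 (SE 0.26) that was -0.16 without WT 4 and -0.01 without KO 6. Itgb1 (ENSMUSG00000025809, chromosome 8, 128685654 to 128733200) was at 156 ± 23.8 and 140 ± 5.69 CPM, a log2 fold change of -0.16 (SE 0.13) that was 0.003 without WT 1 (n = 2 each). The 4 genes of the study were also tested as a list, with a median of -1.24, 3 lower and 1 higher. Adjusted over the list alone, edgeR called 2 of the 4 (Cd93 and Zfp503), against 0 over all genes. The study picked these genes, so the list is not independent evidence of its direction. By camera of limma it was lower, with an adjusted p of 3.08e-12 (adjusted p = 0.593 with an estimated correlation, and 2.73e-18 to 0.973 over the alternatives).

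**Figure D1:**
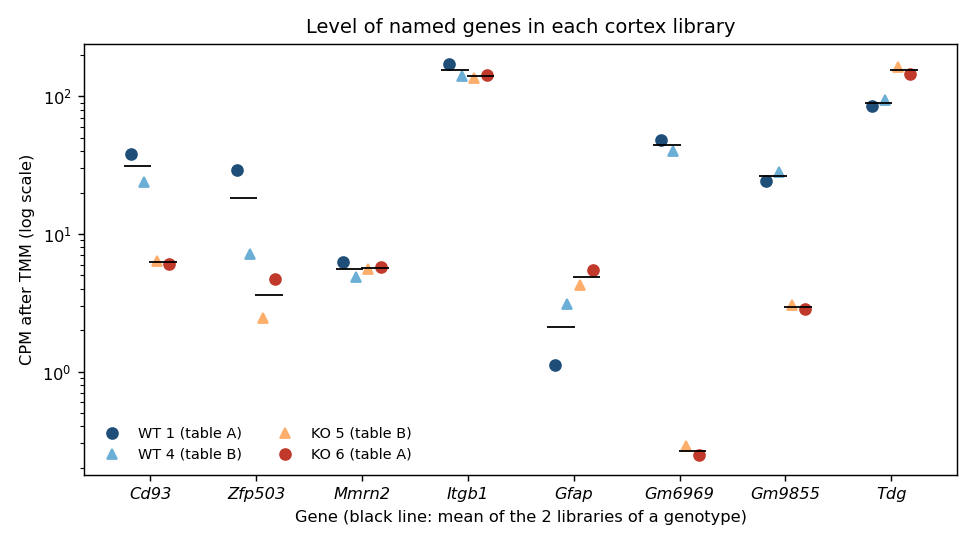
Levels of 8 genes in each library, in CPM after TMM scaling on a log axis, with symbols for the 2 deposited tables and black lines at the mean of the 2 libraries of a genotype. Cd93 was at 31.1 CPM in WT and 6.22 CPM in KO, and the Zfp503 libraries ranged from 29.1 CPM in WT 1 to 2.46 CPM in KO 5.

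Across the genome, 2 genes passed the edgeR test as lower in the KO and 0 as higher, and both are processed pseudogenes, retrocopies of expressed genes. Gm6969 (ENSMUSG00000066553, chromosome 12, 24638669 to 24639010) had 854 and 686 counts in WT 1 and WT 4 against 5 and 4 in KO 5 and KO 6, a log2 fold change of -7.33 (SE 0.24, edgeR adjusted p 0.000402). Gm9855 (ENSMUSG00000085666, chromosome 10, 42054113 to 42055306) had 433 and 478 counts against 53 and 46, a log2 fold change of -3.16 (SE 0.19, edgeR adjusted p 0.0101). Their sequences overlap those of Cox7a2l, a gene of a respiratory chain factor, and Tdg, a gene of a DNA repair glycosylase, in 82.4% and 85.8% of 25-base words. Counts of these copies are therefore uncertain. With the crossed block, KO 6 with WT 4, Gm9855 had an edgeR adjusted p of 0.0776, the highest over the alternatives, which began at 2.86e-26. Among protein-coding genes alone edgeR called 0. Of the 16371 tested genes 317 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance gives. DESeq2 called 9 genes (2 higher, 7 lower) and limma-voom 2. Leaving out a library moved the edgeR count to 44 without WT 1, 312 without WT 4, 5 without KO 5 and 8 without KO 6. The libraries of the genotypes did not overlap in 23.4% of genes, where chance gives 33.3%.

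The genes of smallest p that did not pass were led by Tdg, the lincRNA Gm42047 and Cbs among those higher in KO. Tdg was at 89.6 ± 6.35 CPM in WT and 155 ± 13.3 CPM in KO, a log2 fold change of 0.79 (SE 0.12). Gm42047 was at 271 ± 51.3 and 510 ± 38.1 CPM (n = 2 each). Cbs, the gene of the transsulfuration enzyme cystathionine beta-synthase, had a log2 fold change of 0.97 (SE 0.21), 0610040J01Rik 1.77 (SE 0.42), Htra1, the gene of a secreted serine protease, 0.67 (SE 0.17), and Ppp1r16b, the gene of a phosphatase regulatory subunit, 0.46 (SE 0.10). Without WT 1 edgeR called Cbs, at 1.18 with an adjusted p of 0.0359, and without WT 4 it called 0610040J01Rik, at 2.39 with 0.00732, Tdg, at 0.87 with 0.00448, and Gm42047, at 1.12 with 0.000485. DESeq2 on all 4 libraries called Tdg, with an adjusted p of 0.00015, and Gm42047, with 4.84e-05. Over the alternatives the adjusted p of each of the 4 ran up to 1. On the lower side stood AL607105.1 at -2.78 (SE 0.29) and Rps18-ps3 at -5.05 (SE 0.59). Both share 25-base words with Rps18, 73.2% and 82.6% of their own, and edgeR called both without WT 1, at -3.08 and -5.62, and without WT 4, at -2.40 and -4.08. DESeq2 on all 4 libraries also called both, with adjusted p values of 1.75e-13 and 1.52e-06. So did edgeR with the table as a block, with 0.0009975 and 0.0001375, where the alternatives ran up to 0.9998. Cd36, the gene of a fatty acid receptor, had 17 and 15 counts in WT 1 and WT 4 and 1 and 1 in KO 5 and KO 6. The ratio of its summed counts, KO to WT at equal depth, was 0.0641 (95% counting interval 0.00744 to 0.251), and its fitted log2 fold change, which depends on the prior count, was -3.95 to -3.41 over the alternatives. Cd36 did not pass in edgeR, with an adjusted p of 0.9999, and blocked limma-voom alone called it, with an adjusted p of 0.0466, where the alternatives ran up to 1.

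With the deposited table as a block, edgeR called 29 genes, 2 higher (Tdg and Gm42047) and 27 lower. This fit estimates a table term beside genotype, so little is left to estimate the spread. The table term takes up differences that the libraries of a table share. For ganglionic eminence genes these were medians of 1.01 for WT 1 over WT 4 and 0.68 for KO 6 over KO 5. The crossed block gave 1 call. Among the 29, the lower genes, apart from Cd93, Zfp503 and retrocopies, were chosen for naming after their values were seen. They include ventral forebrain transcription factors, Isl1 at -2.12, Dlx5 at -1.19, Dlx2 at -1.10, Dlx1 at -0.69, Ebf1 at -1.41, Six3 at -2.52 and Nkx2-1 at -2.93, and the GABA-synthesis genes Gad2 at -0.78 and Gad1 at -0.66. They also include Lum at -2.97, Aldh1a2 at -3.52, Col1a1 at -2.31, Col1a2 at -2.40, Col3a1 at -2.73, Dcn at -2.49, Igf2 at -1.66 and H19 at -1.59 (all blocked log2 fold changes), genes of connective tissue, retinoic acid synthesis and embryonic growth. Of the 29, 7 were among the 22 ganglionic eminence and striatum genes and 7 among the 16 meninges and fibroblast genes, where 0.039 and 0.0283 were expected (Fisher's exact test, adjusted p 8.59e-14 and 1.16e-14 over the lists). Interneurons (3 of 18, adjusted p 5.48e-05), study genes (2 of 4, 0.000186) and retinoic acid genes with Zfp503 relatives (2 of 16, 0.00294) also passed it. The hits among the study genes are the knocked-out Cd93 and Zfp503, and Zfp503 counts again in the last list. Fisher's exact test treats genes that vary together as independent, and for each of these 5 lists blocked camera of limma gave adjusted p = 0.837 with an estimated correlation. That setting also called a moved list in 0 of 3 simulations, so this value does not decide. Dlx1, Six3, Igf2 and Tdg overlap other annotated genes, and the strand setting of the counting is not given, so reads of their partners cannot be told apart.

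Genes of the ganglionic eminence and striatum, the ventral forebrain next to the cortex, were lower in the KO as a group. Of 22 tested, 19 were lower and 3 higher, with a median log2 fold change of -1.06. Dlx5, a homeobox gene of the ventral forebrain, was at 26.3 ± 10.4 CPM in WT and 11.3 ± 2.54 CPM in KO, and Dlx1, its most abundant relative, at 229 ± 105 and 138 ± 41.4 CPM (n = 2 each). Six3, a forebrain homeobox gene, had a log2 fold change of -2.90 (SE 0.87), Drd2, the gene of a dopamine receptor of striatal neurons, -1.72 (SE 0.52), and Ebf1 -1.39 (SE 0.43). The median was -1.09 in table A and -0.77 in table B, with 18 genes lower in both. It also differed within genotypes, by 1.01 between WT 1 and WT 4 and by 0.68 between KO 6 and KO 5, and it was -0.06 for KO 6 against WT 4. Camera of limma gave an adjusted p of 2.41e-21 (adjusted p = 0.593 with an estimated correlation, 8.84e-59 to 0.973 over the alternatives). Interneuron genes, 12 lower and 6 higher of 18, had a median of -0.16, 0.05 in table A and -0.31 in table B. Nkx2-1, a transcription factor of the medial ganglionic eminence, had a log2 fold change of -3.15 (SE 0.88), Gad1 -0.70 (SE 0.32) and Calb2, the gene of calretinin, 0.75 (SE 0.20). The interneuron list passed with a camera adjusted p of 0.0405 (adjusted p = 0.820 with an estimated correlation, 6.76e-06 to 0.973 over the alternatives), which was 0.435 without WT 1 and, in the other direction, 0.322 without KO 5.

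Genes of Cajal-Retzius cells and the cortical hem, the early signalling cells at the surface and medial edge of the cortex, were higher in the KO as a group. All 14 tested genes were higher, with a median of 0.37, 0.62 in table A and 0.24 in table B, and 9 were higher in both tables. Calb2 was at 19.02 ± 5.01 CPM in WT and 32.0 ± 2.28 CPM in KO, and Rspo2, the gene of a Wnt-enhancing secreted protein, at 7.30 ± 3.96 and 13.9 ± 2.56 CPM (n = 2 each). Ebf3 and Trp73, transcription factor genes of Cajal-Retzius cells, had log2 fold changes of 0.43 (SE 0.18) and 0.29 (SE 0.13). The list median was also lower in WT 1 than in WT 4, at a log2 ratio of -0.51. Camera of limma gave an adjusted p of 2.83e-11 (adjusted p = 0.593 with an estimated correlation, 4.49e-16 to 0.973 over the alternatives). The thalamus and diencephalon list, of which 9 genes were tested, 6 higher and 3 lower, had a median of 0.36, but -0.04 and 0.18 within the tables. Its camera adjusted p was 0.0405 (adjusted p = 0.593 with an estimated correlation, 0.0103 to 0.973 over the alternatives), 0.619 without WT 1 and 0.165 without KO 5.

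Meningeal and fibroblast genes, among them fibrillar collagens, had the lowest list median in the KO. Of 16 tested, 15 were lower and 1 higher, with a median log2 fold change of -2.05, and adjusted over the list alone edgeR called 6, all lower, against 0 over all genes. Col1a1 was at 52.2 ± 41.9 CPM in WT and 8.80 ± 0.236 CPM in KO, Col3a1 at 86.9 ± 99.5 and 8.79 ± 2.82 CPM, and Lum, the gene of the matrix proteoglycan lumican, at 8.10 ± 7.96 and 0.937 ± 0.680 CPM (n = 2 each). The median was -2.39 in table A and -0.67 in table B, with 12 genes lower in both. Between the WT libraries it differed by 2.54 and between the KO libraries by 0.67, and it was -0.05 for KO 6 against WT 4. Camera of limma gave an adjusted p of 2.41e-21 (adjusted p = 0.593 with an estimated correlation, 2.30e-139 to 0.973 over the alternatives). The list of retinoic acid genes and Zfp503 relatives had a median of -0.53, 14 lower and 2 higher of 16, with Aldh1a2, a retinoic acid synthesis gene, at -3.76 (SE 1.53). Its medians were -0.58 and -0.16 within the tables and its camera adjusted p 3.45e-07 (adjusted p = 0.593 with an estimated correlation, 5.47e-18 to 0.973 over the alternatives), or 0.311 without WT 1.

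Vessel and macrophage genes were lower in the KO as groups, and the difference lay mostly against WT 1. Of 27 endothelial genes 23 were lower and 4 higher, with a median of -0.29, -0.64 in table A and 0.02 in table B. Across tables the endothelial median was -0.67 for KO 5 against WT 1 and 0.08 for KO 6 against WT 4. These cross-table medians were -0.655 and 0.04 for pericytes and -0.78 and -0.09 for microglia. Abcb1a, the gene of the efflux pump P-glycoprotein, had a log2 fold change of -1.05 (SE 0.31), with -1.02 and -1.001 within the tables. Cdh5, the gene of VE-cadherin, had -0.94 (SE 0.42), with -1.43 and -0.11 within the tables. Pericyte and mural cell genes, 11 lower and 2 higher of 13, had a median of -0.34 (-0.60 and -0.07 within the tables). All 20 microglia and macrophage genes were lower, 12 of them in both tables, with a median of -0.48 (-0.78 and -0.12 within the tables). Mrc1, a mannose receptor gene of border macrophages, was at 11.3 ± 13.1 CPM in WT and 2.05 ± 1.20 CPM in KO, and Tmem119, a microglial gene, at 3.49 ± 1.28 and 1.71 ± 0.326 CPM (n = 2 each). Camera of limma gave adjusted p values of 3.73e-07, 0.000358 and 7.02e-09 for the lists of endothelial cells, pericytes and microglia (adjusted p = 0.751, 0.751 and 0.593 with an estimated correlation). Without WT 1 the calls ended, at 0.591 and 0.723 in the other direction for endothelial cells and pericytes and at 0.294 for microglia. Over the alternatives the 3 adjusted p ran from 4.49e-16, 4.31e-12 and 7.00e-18 up to 0.973.

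**Figure D2:**
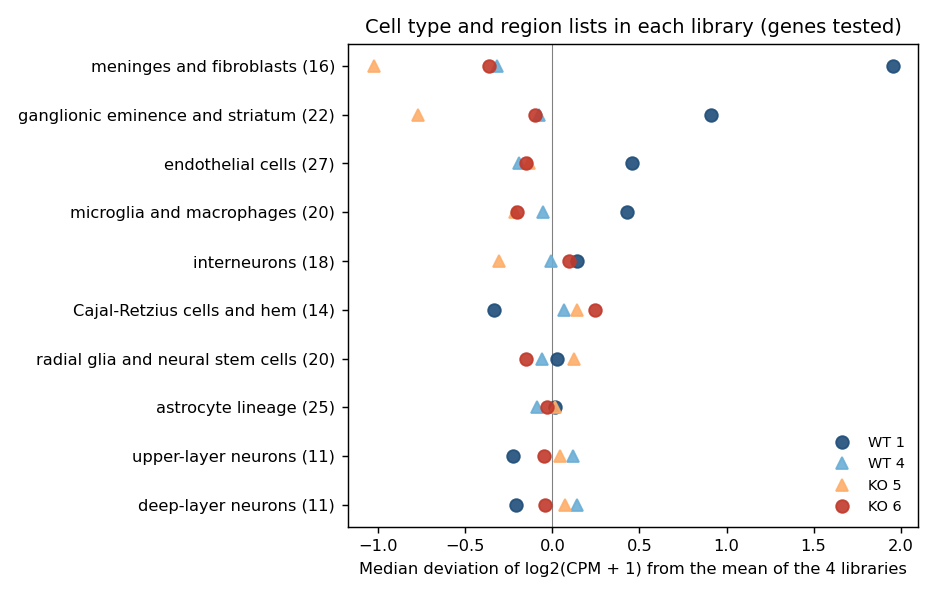
Median deviation of each of 10 cell type and region lists from the mean of the 4 libraries, in log2(CPM + 1), with 1 symbol per library. WT 1 stands apart for meninges and fibroblasts at 1.95 (-0.36 to -0.32 in WT 4 and KO 6, -1.03 in KO 5) and for ganglionic eminence and striatum at 0.91, whereas astrocyte lineage medians lie between -0.09 and 0.02.

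Astrocyte lineage genes, which bear on the study's question, did not pass as a list with all 4 libraries. Of 25 tested, 14 were higher and 11 lower, with a median log2 fold change of 0.02, -0.04 in table A and 0.15 in table B, and a camera adjusted p of 0.878 in limma. Without WT 4 the list passed as lower in KO, with an adjusted p of 0.00999, and without WT 1 it leaned higher, with 0.0783, within 0.00999 to 0.9999 over the alternatives. Higher in both tables were 9 genes, lower in both 5, and 11 went opposite ways. Gfap, the intermediate filament gene of astrocytes, had 20 counts in WT 1, 53 in WT 4, 75 in KO 5 and 89 in KO 6, or 2.12 ± 1.41 CPM in WT and 4.88 ± 0.852 CPM in KO (n = 2 each). Its log2 fold change of 1.20 (SE 0.48) did not pass, with an edgeR adjusted p of 0.9999, and it was 2.17 and 0.45 within the tables. Slc1a2, the gene of the glial glutamate transporter, had a log2 fold change of 0.35 (SE 0.13), Acsbg1 -0.52 (SE 0.23) and Gjb6, the gene of connexin 30, -2.79 (SE 1.26). Gjb6 was at 3.98 ± 4.88 CPM in WT, where its libraries lay far apart, and at 0.581 ± 0.660 CPM in KO (n = 2 each). The mean of the list's members was -0.14, of the other sign than its median.

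Lists of the cortical neural lineage did not pass with all 4 libraries either. Medians were -0.03 for 20 radial glia and neural stem cell genes, 0.03 for 11 intermediate progenitor genes, -0.08 for 12 oligodendrocyte lineage genes, 0.06 for 11 upper-layer and 0.05 for 11 deep-layer neuron genes, and 0.03 for 20 pan-neuronal genes. Eomes, the marker gene of intermediate progenitors, was at 134 ± 28.9 CPM in WT and 153 ± 47.3 CPM in KO, and Sox2, a stem cell factor gene, at 103 ± 31.4 and 86.9 ± 4.59 CPM (n = 2 each). Among deep-layer genes Foxp2 had -0.49 (SE 0.17), with -0.46 and -0.51 within the tables, and Bcl11b -0.31 (SE 0.11), with -0.44 and -0.19. Camera adjusted p values in limma were 0.880, 0.488, 0.391, 0.260, 0.993 and 0.119 in the order of the lists. Leaving out a library gave calls in each of the 6. Intermediate progenitor and radial glia genes were lower without KO 5 (0.00571 and 0.0326) and higher without KO 6 (1.76e-05 and 0.0212). Oligodendrocyte genes were lower without WT 4 (0.000421) and without KO 6 (0.0148), upper-layer and deep-layer genes higher without WT 4 (0.0245 and 0.0414), and pan-neuronal genes higher without KO 5 (0.0115). Over the alternatives the highest adjusted p of these lists was 0.973 to 1. Other tissue lists that did not pass with all 4 libraries were hippocampus (median -0.06), choroid plexus (-0.19), ependymal and ciliated cells (-0.03), erythroid blood cells (0.09) and muscle, skin and bone (0.03). By camera of limma muscle, skin and bone genes were lower without WT 1 (adjusted p 1.27e-11), choroid plexus genes without WT 4 (0.00062) and KO 6 (0.0357), and erythroid genes without KO 6 (0.0298), each up to 0.9999 over the alternatives. Of all 41 lists, 7 had a median, mean and test of differing sign, and 0 of these passed.

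Among pathways, cell cycle, adhesion and complement genes were lower in the KO as groups and Wnt genes higher. Of 30 cell cycle genes 26 were lower and 4 higher, with a median of -0.15, but -0.41 in table A and 0.08 in table B, and 22 went opposite ways in the tables. Kif11, a spindle motor gene, was at 73.2 ± 11.1 CPM in WT and 53.7 ± 8.74 CPM in KO (n = 2 each). Integrin and focal adhesion genes had a median of -0.16 (22 lower, 5 higher), -0.47 and 0.11 within the tables. The 15 CD93 family and C-type lectin relatives had -0.17 (10 lower, 5 higher), -0.42 and 0.06 within the tables, and adjusted over the list alone edgeR called 1, Cd93. This list holds the knocked-out gene itself and was not tested without it, so its call is partly set by the design. Complement genes had -0.24 (8 lower, 2 higher), -0.45 and 0.04 within the tables. Wnt signalling genes had 0.15 (23 higher, 6 lower), 0.10 and 0.23 within the tables, with Axin2, a feedback target of the pathway, at 0.27 (SE 0.12). Camera of limma gave adjusted p values of 0.000195, 0.000442, 6.93e-07, 0.0194 and 0.000232 in that order (adjusted p = 0.820, 0.751, 0.593, 0.751 and 0.751 with an estimated correlation). Without WT 1 these calls ended, at 0.309, 0.723, 0.131, 0.723 and 0.294, with integrin and complement genes in the other direction. The cell cycle call turned without KO 6 (0.271), the integrin call ended without KO 6 (0.0951) and the Wnt call without KO 5 (0.934). Over the alternatives the lowest adjusted p were 1.17e-14, 9.56e-07, 1.99e-09, 2.46e-06 and 8.38e-08, and the highest 0.973 in each.

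Antigen presentation genes and hypoxia and glycolysis genes were higher as groups, and immediate early and dissection stress genes lower. Of 5 antigen presentation genes 4 were higher, with a median of 0.33 (0.42 and 0.58 within the tables), and H2-D1, a class I gene, was at 5.80 ± 6.04 CPM in WT and 16.4 ± 1.248 CPM in KO (n = 2 each). Hypoxia and glycolysis genes had 0.12 (14 higher, 5 lower), 0.09 and 0.11 within the tables. Stress genes had -0.11 (13 lower, 6 higher), -0.17 and 0.05 within the tables, with Klf4, an immediate early transcription factor gene, at -1.22 (SE 0.34). Camera of limma gave adjusted p values of 0.00403, 0.0407 and 0.0194 (adjusted p = 0.593, 0.593 and 0.781 with an estimated correlation). The antigen presentation call ended without WT 4 (0.348) and without KO 6 (0.0996), the hypoxia call without any 1 of WT 1, WT 4, KO 5 and KO 6 (0.0863, 0.352, 0.165 and 0.0780), and the stress call without WT 4 (0.270) and KO 6 (0.901). Over the alternatives the adjusted p ran from 3.33e-06, 0.0228 and 0.00101 up to 0.973. JAK/STAT genes, the pathway of astrocyte induction by cytokines, had a median of -0.09 and a camera adjusted p of 0.579, with Stat3 at 0.29 (SE 0.12). Other lists that did not pass with all 4 libraries were BMP and SMAD signalling (median -0.02), Notch signalling (0.00), angiogenesis and VEGF (-0.12), interferon response (-0.09), cholesterol synthesis (0.04), the 18 genes around Cd93 (0.04), mitochondrial genome (0.07), cytosolic ribosomal proteins (0.02), replication-dependent histones (0.07) and the 1 tested sex-linked gene, Xist (0.04). Among these, camera of limma called mitochondrial genome genes higher without WT 1 (adjusted p 1.39e-07) and KO 5 (2.29e-09) and lower without WT 4 (0.0472) and KO 6 (1.76e-05). Ribosomal protein genes were higher without WT 1 (0.000726) and KO 5 (4.03e-07) and lower without KO 6 (0.0055). Notch genes were lower without KO 5 (0.0493), angiogenesis genes lower and cholesterol genes higher without WT 4 (0.00747 and 0.0423), and histones higher without WT 4 (0.0104) and KO 6 (0.0357). The highest adjusted p of these lists over the alternatives was 0.973 to 0.9999.

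In all, 18 of 41 lists passed with the preset correlation, 5 higher and 13 lower, and 0 with the estimated correlation or with fry of limma. In simulations the estimated correlation also called a moved list in 0 of 3. Lists share genes, so these calls are not all separate. Another list holds 6 of 9 tested thalamus genes, 5 of 14 Cajal-Retzius genes and 6 of 29 Wnt genes. The same is true of 5 of 15 CD93 family genes and 9 of 27 endothelial genes. The lists of the study genes, ganglionic eminence and striatum, Cajal-Retzius cells and hem, and meninges and fibroblasts passed in each of the 4 fits that left out a library. No list held a gene that edgeR called over all genes without a block. The lists other than study genes, meninges and fibroblasts, and CD93 family held 0 called genes adjusted over the list alone. Of the tested genes 317 had an unadjusted p under 0.05, a smaller share than chance gives. DESeq2 called 9 genes and limma-voom 2. With the table as a block edgeR called 29, of which several are in lists as given above. Without WT 1, 9 lists passed, and 24, 20 and 21 without WT 4, KO 5 and KO 6. Of the 23 lists that did not pass with all 4 libraries, 16 passed in a fit that left out a library, 4 of them in both directions, and 0 under the other alternatives.

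**Figure D3:**
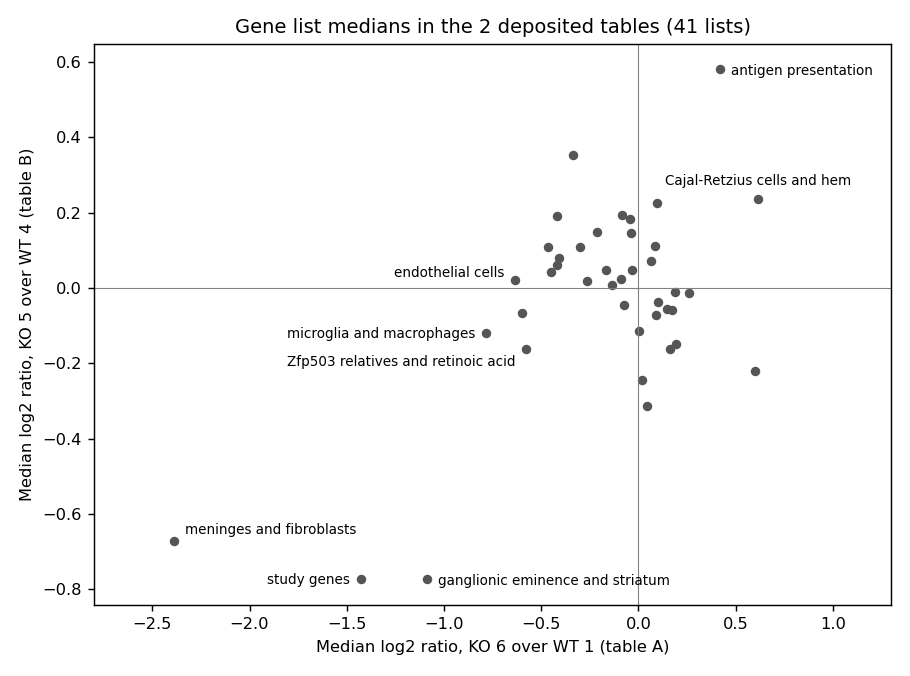
Median log2 ratio of KO to WT of each of the 41 gene lists within table A (horizontal axis) and within table B (vertical axis). Meninges and fibroblasts, at -2.39 and -0.67, the study genes, at -1.43 and -0.77, and ganglionic eminence and striatum, at -1.09 and -0.77, lie lowest in both, and endothelial cells are at -0.64 and 0.02.

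The 2 tables share no library, and across genes their log2 ratios were nearly unrelated. Over 16371 genes Pearson's r was 0.013 and Spearman's rho -0.072, and 45.1% of genes had the same sign. Genes are not independent replicates, so these values describe the libraries. With the libraries paired the other way, KO 6 with WT 4 and KO 5 with WT 1, r was -0.213. Libraries of a table deviated alike: the ratio of WT 1 to WT 4 and that of KO 6 to KO 5 had an r of 0.224 across genes. The covariance behind this r is set by those of the within-table and crossed ratios, so it is not a separate observation.

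In the authors' deposited tables, which compare single libraries, 4674 genes had an adjusted p under 0.05 in table A (1749 higher in KO, 2925 lower) and 2788 in table B (1376 higher, 1412 lower). Of the genes in both tables, 192 were lower in both, where independent lists would share 186.4, and 167 higher in both, where 117 were expected. Those called in opposite directions were 319 and 449, against 112.7 and 193.6 expected. With the authors' 2-fold minimum the calls numbered 1028 and 502, and 45 genes were then lower in both, where independent lists would share 9.3, and 5 higher in both, where 1.7 were expected. Genes called in opposite directions numbered 17 and 14, against 2.9 and 5.5 expected. In the authors' deposited tables Cd93 had a log2 fold change of -2.67 in table A and -1.91 in table B, and Zfp503 -2.64 and -1.54, and both were marked in both. Gfap in the authors' deposited tables had 2.26 in table A, where it was marked, and 0.47 in table B, where it was not.

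Gene ontology terms gave no enrichment among the 2 genes edgeR called: 0 of 1897 terms passed a hypergeometric test, which has little to work with at 2 genes. Camera of limma over the same terms, added after the data were seen, called 16, of which 15 were lower and 1 higher, and 0 with an estimated correlation (adjusted p = 0.999 with an estimated correlation for each). Among those called lower, regulation of oxidative phosphorylation, with 10 genes and a camera adjusted p of 0.000173, had a median of 0.113, of the other sign than its call.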

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

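All tests in this part were chosen after the results were seen. Some genes are listed in 1 table only, and so are outside the tested genes, apart from an alternative that set absent genes to 0. Counting those with over 20 counts in a library and 3 or fewer in its table partner gave 45 genes for WT 4, 5 for WT 1, and 0 for KO 5 and for KO 6. In WT 4 they include genes known from the outer skin, such as the keratin genes Krt5 and Krt14 and the cornified envelope gene Ivl, chosen after their values were seen, and no test of this theme was made. The highest counts were 452 for Hrnr, 334 for Calm4, 300 for 2310034C09Rik and 288 for Krt14. In WT 1 the 5 genes were Dio3, Foxd2, Gbp4, Mrgprf and Osr1, and Osr1, a mesenchymal transcription factor gene, had 71 counts.

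The ganglionic eminence and striatum list was lower in the KO. A candidate explanation is a different share of ganglionic eminence tissue in the dissected cortices: between libraries of one genotype the list median differed by at least 0.68 (log2), with WT 1 above WT 4 and KO 6 above KO 5, so the list moves without a change of genotype. Zfp503 lay outside the range of the list's members in 0 of 4 ratios within tables and within genotypes. That range was wide, -3.28 to 0.405 in KO 6 against WT 1, so lying inside it decides little. The lower Zfp503 in the KO may move with the share of ganglionic eminence tissue. However, only 1 of 22 members was as low as Zfp503 in KO 6 against WT 1 and 5 in KO 5 against WT 4. Across tables, Zfp503 was at -0.58 for KO 6 against WT 4, where the list median was near 0 and 1 of 22 members was as low. For KO 5 against WT 1 it was at -3.51, with 4 of 22 as low. Loss of Cd93 stays open. Within tables A and B the list median was -1.09 and -0.77, with 19 of 22 members lower in each. The highest list median over the 4 pairings of a KO with a WT library was -0.058, close to 0, for KO 6 against WT 4 across tables. Both gaps within a genotype also run from table A to table B, so a run or day shared by a table is not separated. With 2 libraries per genotype loss of Cd93 cannot be told apart from dissection. The list's most abundant gene, Dlx1, was at 229 CPM in WT and 138 CPM in KO, 22 of its 24 genes were tested and 3 are held by another list.

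The meninges and fibroblast list was lower in the KO. A different share of meninges left on the dissected cortices may account for it, since the list median differed by at least 0.67 (log2) between the libraries of either genotype, with WT 1 above WT 4 by 2.54. Loss of Cd93 stays open. Within tables A and B the list median was -2.39 and -0.67, with 15 and 12 of 16 members lower. The highest list median over the 4 pairings was -0.05, for KO 6 against WT 4 across tables. With 2 libraries per genotype loss of Cd93 cannot be told apart from the share of meninges, or from a run or day shared by a table. The list's most abundant genes were Igf2, at 181 ± 188.5 CPM in WT and 43.7 ± 25.3 CPM in KO, and Fn1, at 144 ± 60.8 and 108 ± 3.22 CPM (n = 2 each), and 3 of the list's genes are held by another list.

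The retrocopies Gm6969 and Gm9855 were the only genes that edgeR called without a block. DNA of another strain kept around Cd93 is argued against as their common cause, since 0 of the 2 lie on its chromosome, while a strain difference elsewhere was not tested. Reads of Cox7a2l counted for Gm6969 in WT and for Cox7a2l in KO may account for the first, because the CPM gained by Cox7a2l was 89.0% of that lost by Gm6969. For reads of Tdg counted for Gm9855 the gain of Tdg was 282% of the loss, more than such a transfer gives. The summed CPM of Tdg and Gm9855 was 116 ± 8.98 in WT and 158 ± 13.5 in KO (SD, n = 2 each, difference 42.5 CPM, SD 16.2). For the higher Tdg, this sum argues against moved reads of Gm9855 alone only if each shared read was counted for either gene. How reads that fit both genes were counted is not given. If such reads were left out, the sum need not stay the same, so a mapping cause of the higher Tdg stays open. For the fall of Gm9855 a transfer to Tdg stays open and cannot be told apart from a loss of its own reads, since counts do not show where its reads went. Pseudogene differences between libraries that do not follow genotype were also seen: of 614 pseudogenes with 20 or more counts in a library, at a pseudocount of 0.1 CPM, 3 were parted 4-fold or more by genotype, 14 by table and 5 by the crossed pairing. These counts cover pseudogenes of every kind, not retrocopies alone. Gm29216, parted by table, is an unprocessed pseudogene, while Gm8730 and Gm9625, parted by the crossed pairing, are processed ones.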

How the results depend on the processing

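The alternatives added after the data were seen were genes of either table, protein-coding genes only, the blocked limma-voom and DESeq2, DESeq2 and limma-voom for Cd93, the estimated correlation with a block, and camera over the terms. The count of 2 called genes kept within 1.5 times under 8 of 18 alternatives. It was 9 with DESeq2, 29 with the deposited table as a block, 1 with the crossed block, 45 with blocked limma-voom and 21 with blocked DESeq2. For protein-coding genes only it was 0, with 281 at an unadjusted p under 0.05, a smaller share than chance gives. Leaving out 1 library gave 5 to 312, and there the lone library of a genotype is assumed to vary like the other group. Cd93 was lower under each alternative, and past the threshold at -2.29 with the table as a block, -2.32 with DESeq2, and -2.30 and -2.28 with blocked limma-voom and blocked DESeq2. It was -2.61 to -1.95 over the fits without 1 library, past the threshold without WT 1 or WT 4 and not without KO 5 or KO 6 (edgeR adjusted p 0.246 and 0.257, from 4.13e-09). Mmrn2 turned to -0.16 without WT 4 and -0.01 without KO 6 (-0.16 to 0.21 over the fits without 1 library), and Itgb1 to 0.003 without WT 1 (-0.31 to 0.003). Of the other 12 named genes, none changed direction over these alternatives. The 18 lists past the threshold became 0 with an estimated correlation (with or without a block), 0 with fry, directional and mixed, and 9 to 24 without 1 library, where 16 of the other 23 lists passed at least once, 4 of them in both directions. Lists that turned direction were interneurons without KO 5 (adjusted p 0.322 by camera of limma, 6.76e-06 to 0.435 over the fits without 1 library), endothelial cells without WT 1 (0.591, from 4.49e-16), pericytes (0.723, from 4.31e-12), integrin (0.723, from 9.56e-07) and complement (0.723, from 2.46e-06) likewise, and cell cycle without KO 6 (0.271, within 1.17e-14 to 0.309). The r across tables turned to -0.213 in crossed pairs. The authors' calls numbered 1028 and 502 with a 2-fold minimum and 2228 and 987 at an adjusted p of 0.001, since these thresholds are stricter. Camera over the terms called 16, where the test of called genes called 0. The estimated correlation adds the genes' shared variation to the error, and a left-out library means fewer samples. For the other values the cause was not tested. Pseudocounts of 0.1 and 5 were not run for the changed genes, whose test uses counts, and a prior count of 0.5 gave an r across tables of 0.008. Depth limits genes near 3 counts (0.171 to 0.184 CPM), such as Cd36.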

Other observations

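All tests in this part were chosen after the results were seen. Some skin genes, each chosen after its values were seen, stood out in WT 4 also among genes listed in both tables. Krt1, a keratin gene of the upper epidermis, had 1990 counts in WT 4 against 121, 123 and 134 in WT 1, KO 5 and KO 6, Krt10 had 912 in WT 4 and 132 in KO 6, and Lor, the gene of the cornified envelope protein loricrin, had 517 against 11, 12 and 13. Of the terms that camera of limma called, peptide cross-linking, with 11 genes, had the smallest adjusted p, 1.16e-07, and a median of -1.16 (-0.72 in table A, -0.97 in table B). Keratinocyte differentiation, with 27 genes, had 0.00222. Blood vessel development, with 52 genes and a median of -0.07 (-0.31 and 0.06 within the tables), had 0.00449, and cell adhesion mediated by integrin, with 13 genes and a median of -0.27 (-0.61 and 0.02 within the tables), had 0.0313. The single term that was higher, class I antigen processing, had 17 genes, a median of 0.11 and an adjusted p of 0.0322. For each of these terms the adjusted p was 0.999 with an estimated correlation.

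Some genes of the cortical hem, the signalling centre at the medial edge of the cortex, had their lowest counts in WT 1, and the 3 given were chosen after their values were seen. Wnt8b had 16 counts in WT 1, 103 in WT 4, 174 in KO 5 and 105 in KO 6, Wnt3a had 5, 43, 59 and 40, and Rspo1 had 13, 73, 110 and 64 in the same order. Reln, the gene of the matrix protein reelin of Cajal-Retzius cells, had 7314, 6516, 6984 and 7366 counts, not lowest in WT 1. The meningeal genes Slc6a13, a GABA transporter gene, and Cldn11, a tight junction gene, had 448 and 456 counts in WT 1, 3 and 11 in WT 4, 4 and 6 in KO 5, and 52 and 35 in KO 6.

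Some genes split the libraries by table or across both table and genotype. The pseudogene Gm29216 had 4809 and 4912 counts in WT 1 and KO 6 against 225 and 211 in WT 4 and KO 5. The mitochondrial gene mt-Co3 had 3224 and 3471 against 793 and 768, and Ttr, the transthyretin gene of the choroid plexus, 178 and 222 against 8 and 17. The pseudogene Gm8730 had 5280 and 4776 counts in WT 4 and KO 6 against 150 and 161 in WT 1 and KO 5, and Gm9625 had 605 and 655 against 11 and 10. Rps18, a ribosomal protein gene, was instead higher in both KO libraries than in both WT libraries, and its WT libraries lay far apart. It had 3562 counts in WT 1, 732 in WT 4, 5576 in KO 5 and 6507 in KO 6. Rps18 did not pass in edgeR, with an adjusted p of 0.9999. Rps18-ps3 and AL607105.1, which share sequence with Rps18, were highest in WT 4, where Rps18 was lowest. In the same order they had 298, 828, 15 and 18 counts, and 305, 468, 52 and 57. The CPM gained by Rps18 was 750% and 1247% of that lost by each. How reads that fit several genes were counted is not given, so a change of Rps18 cannot be told apart from reads counted differently.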
